A study of Mus musculus with 8 samples.

How the data were processed

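RNA was sequenced from whole hearts of 8 wild-type C57BL/6J mice, 4 male and 4 female. Per the labels' protocols, single hearts were dissected in cold buffer, homogenized in Trizol, and extracted with a kit that the protocol describes as isolating small RNA, while the molecule field names total RNA. Libraries followed a standard Illumina protocol, per the labels. The age is given as 4 weeks in one place and 4 to 6 weeks in another. All 8 hearts carry the same batch label.

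The deposited table held 17911 genes with 1 signal column per heart, which per the values are read counts that the authors divided by 1 size factor per heart. It also held the authors' own log2 fold change and the authors' unadjusted and adjusted p-values for female against male hearts. Per the submitters' processing notes the genome build was mm10; the aligner, the counter, the strand setting, the filter and the authors' test are not given in the sources used here. Every value in every column was a whole multiple of the value of 1 read (100% of values, tolerance 0.001 reads), so whole reads were recovered. They summed to between 51.7 M and 75.7 M reads per heart, below the more than 80 M stated in the labels. Size factors ranged from 0.821 to 1.17. The gene with the fewest reads had 81 over the 8 hearts, so genes of lower count are not analysed here. The authors' adjusted p was NA for 3823 genes and stayed NA.

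Gene positions and types came from the GENCODE vM21 mouse annotation of the same build, matched by gene identifier; 47 identifiers had no match there and belong to no chromosome class below. The table covered 17251 autosomal genes, 575 on chromosome X, 6 on chromosome Y and 32 on the mitochondrial genome.

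The design written before the data were examined assumed counts and edgeR, with limma as the test should the values prove to be normalized. Since the values are normalized, the main test was limma 3.58.1 (trend and robust options, R 4.3.3) on log2(value + 1), female minus male, over all 8 hearts with no covariate. A gene entered if its value was at least 1 in 4 or more hearts, which removed 0 genes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p of a single gene is from this limma fit unless another tool is named. Fold changes on this scale understate the change of low genes. Levels are the deposited normalized read counts, given as mean ± SD with n = 4 per sex. Sums of X and Y partner genes were compared by two-sided exact permutation tests over the 70 assignments of the hearts, whose smallest possible p is 0.0286.

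The 38 gene lists were fixed before the data were examined. They covered the sex chromosomes, heart muscle, metabolism, clock and stress genes, hormone response, translation, and markers of other cell types and neighbouring tissues. Each list was tested with camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. The score of a list in a heart was the mean over its members of the log2 value minus the male mean. Genes named in the text were set by a rule of the same date: all measured Y-linked genes and X-linked genes with a Y partner, plus Xist; the 10 autosomal genes with the largest fold change in each direction among called genes without overlap between the sexes, leaving out predicted genes and pseudogenes; and up to 4 members with the smallest p of each list described. Other genes are said to have been chosen after their values were seen.

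Within each sex, the 12 pairs of hearts differed by 8.34 to 18.8 times the sampling noise of their reads (chi-square per degree of freedom), so no library appeared to have been deposited more than once. The tests were tried on simulated data: counts for the 17911 genes of this comparison with 200 changed genes. There limma recovered 52.2% of genes changed 1.25-fold, 77.6% at 1.5-fold and 97.0% at 2-fold, and 8.48% of its calls were false. A list shifted by a log2 of 0.2 had a camera adjusted p = 4.38e-26, and 0 of 35 lists sharing no gene with it were called. Simulated genes were drawn independently of each other, so this check cannot speak for false calls of lists whose genes vary together. In the real data the estimated correlation within a list ran from -0.00866 (sex hormone receptors and steroid enzymes) to 0.841 (MHC class II). It was 0.533 for the macrophage list. The false share of calls was 7.32% for edgeR's quasi-likelihood test, 6.29% for limma-voom and 16.7% for DESeq2.

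Alternatives fixed before the data were examined were edgeR 4.0.16 with RLE or upper quartile factors, DESeq2 1.42.0 and limma-voom on the recovered reads, other pseudocounts and filters, the thresholds stated in the labels, leaving out each heart, blocks by replicate number, and for lists an estimated correlation and fry. Chosen after seeing the data were total reads as a covariate and the 5 hearts with the most reads alone. For a table of counts the design had named edgeR with TMM factors after a filter on low counts. It had also named TMM-scaled CPM for the sum of Ddx3x and Ddx3y. The use of both on the recovered reads was chosen after the values proved to be normalized. The count test with TMM factors and the filter called 216 genes. The same test without the filter was fixed before the data were examined and called 214. The alternatives for a table of fold changes alone did not apply. The genes followed under the alternatives were narrowed after a first run, as given in the closing section.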

Results

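Hearts of 4 male and 4 female wild-type mice were profiled by RNA sequencing to ask which transcripts differ between the sexes. The series title names DDX3X, an X-linked DEAD-box RNA helicase that acts in translation, so Ddx3x and its Y-linked partner Ddx3y are given first. Reads assigned to genes numbered 66.0 M, 66.3 M, 61.6 M and 51.7 M in female replicates 1 to 4. The male libraries held 70.2 M, 74.8 M, 75.7 M and 55.0 M reads in replicates 1, 3, 4 and 5. Depth averaged 61.4 ± 6.81 M reads in females and 68.9 ± 9.60 M in males (SD, n = 4 each).

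Ddx3x was higher in female hearts and Ddx3y was expressed at a substantial level in male hearts alone, while their summed read count was close in the sexes. Ddx3x (chromosome X, 13280970 to 13294052, plus strand, mm10) had a normalized read count of 19651 ± 323 in females and 13424 ± 264 in males (SD, n = 4 each). It rose by a log2 fold change of 0.55 (SE 0.03, limma adjusted p = 9.88e-07), a ratio of 1.46. Ddx3y (chromosome Y, 1260771 to 1286629, minus strand) had 5912 ± 162 in males and 29.4 ± 36.2 in females (limma adjusted p = 0.0113). That call ended without female replicate 2 (adjusted p = 0.0526) and without male replicate 4 (adjusted p = 0.0517), with log2 fold changes of -8.08 and -8.35. The sexes did not overlap: Ddx3y ran from 4.85 to 82.8 in single female hearts and from 5715 to 6111 in single male hearts. In males Ddx3y made up 30.6% ± 0.444 of the summed read count (SD, n = 4). Sums of partner genes, here and below, add reads without correction for transcript length, so they are not sums of transcripts. Whether reads shared by partner genes were counted was not tested. The sum was 19680 ± 327 in females and 19336 ± 389 in males, a difference of 1.78% (exact permutation p = 0.2, n = 4 each, two-sided). Without 1 heart it ran from 1.02% (male replicate 4) to 2.45% (female replicate 1). The 95% interval of the difference from limma ran from -2.53% to 6.29%. In TMM-scaled CPM of the recovered reads, the measure first designed for counts, the sums differed by 1.77% (exact permutation p = 0.2, n = 4 each).

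Other X and Y partner pairs did not show one common pattern. Eif2s3x, a subunit of translation initiation factor eIF2, rose in females (4666 ± 50.3 against 2726 ± 17.7, log2 fold change 0.77, limma adjusted p = 1.74e-08). Its sum with Eif2s3y was 4690 ± 41.2 in females and 6805 ± 93.2 in males, a difference of -31.1% (exact permutation p = 0.0286, n = 4 each, the smallest possible). The histone demethylase gene Kdm5c rose by 0.59, and its sum with Kdm5d was higher in females by 8.79% (exact permutation p = 0.0286). Kdm6a, also a histone demethylase gene, rose by 0.87, and its sum with Uty differed by -10.0% (exact permutation p = 0.0286). The X-linked genes Usp9x, Zfx, Uba1 and Rbmx did not pass the test, with log2 fold changes of 0.04, 0.02, 0.04 and 0.01. The direction turned for Zfx with total reads as a covariate (-0.01) and for Rbmx without female replicate 3 or 4 or male replicate 3 or 4.

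**Figure D1:**
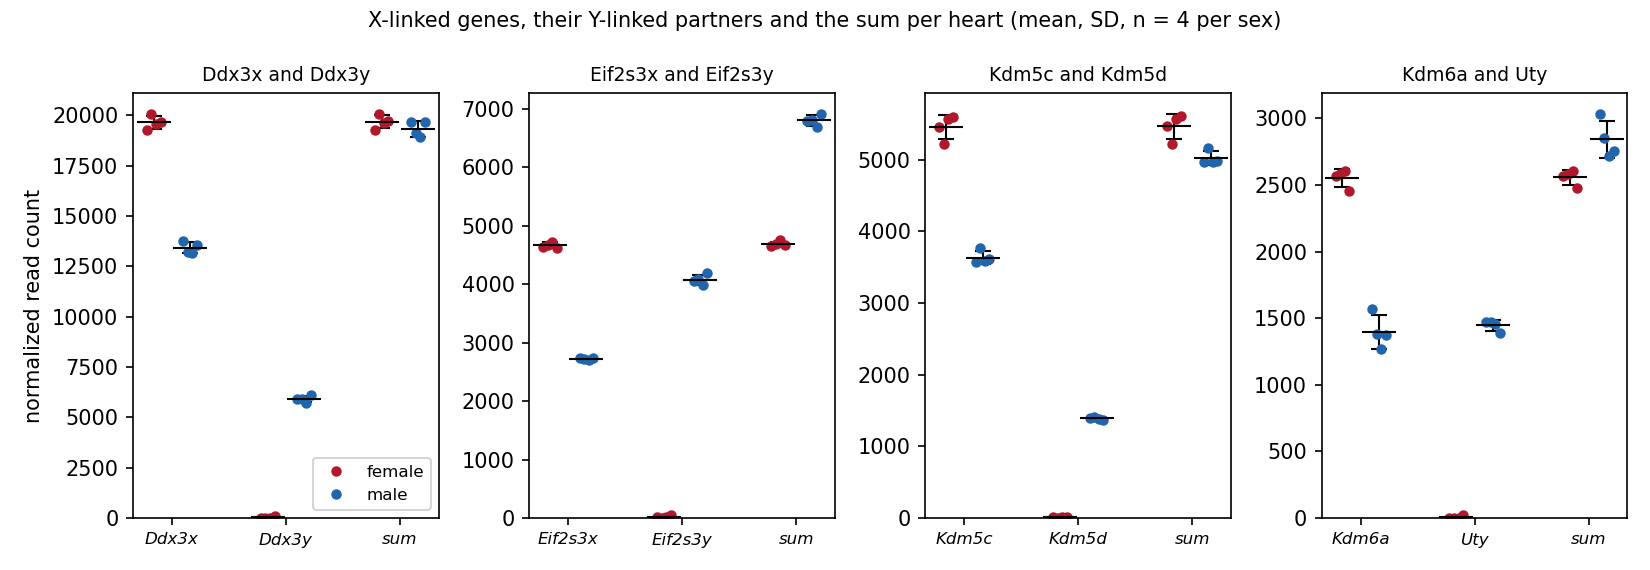
Normalized read counts per heart (vertical axis) of 4 X-linked genes, their Y-linked partners and the sum of each pair, in female and male hearts; points are single hearts, and black lines with bars are the mean and SD of 4 hearts. The Ddx3x and Ddx3y sums overlap between the sexes, while the Eif2s3x and Eif2s3y sums do not.

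Label checks followed the sexes in all 8 hearts. Xist, the RNA that coats the inactive X chromosome, had 14502 ± 340 in females and 235 ± 20.2 in males (SD, n = 4 each). Tsix lies on the opposite strand of Xist, and the strand setting of the counting is not given, so low Xist counts in males cannot be assigned to a strand. Each of the 4 measured Y-linked list genes (Ddx3y, Eif2s3y, Kdm5d and Uty) fell in females. Of the 8 measured X-linked genes with a Y partner 4 rose and 4 did not pass, over all genes and adjusted over the list alone alike. Of the 12 genes of the X inactivation locus and known escape genes 3 rose (Xist, Pbdc1 and 5530601H04Rik) and 9 did not pass; the call of 5530601H04Rik ended in 4 of the 8 fits without 1 heart. Adjusted over the list alone, 6 rose and 1 fell. With an estimated correlation, each of these 3 sex-chromosome lists had an adjusted p = 0.0599.

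Across all genes, 208 differed between female and male hearts, 85 higher and 123 lower in females. Most differences were small: 28 of the 208 exceeded a log2 fold change of 0.6 in size, and the median size was 0.30. Of the calls, 185 were autosomal (71 higher, 114 lower), 16 were on chromosome X (13 higher, 3 lower), 5 on chromosome Y (all lower) and 1 on the mitochondrial genome. Genes on chromosome X were called higher in females more often than autosomal genes (2.26% against 0.412%, odds ratio 5.60, 95% interval 2.82 to 10.3, Fisher's exact p = 2.74e-06). The 13 include the label-check genes Xist, Ddx3x, Eif2s3x, Kdm5c, Kdm6a, Pbdc1 and 5530601H04Rik. The share without them was not tested, and Fisher's test treats genes as independent. The 3 X-linked genes that fell were Apln, Amot and Tmsb4x. They are named after their values were seen, as are the mitochondrial tRNA gene mt-Tc, the Y-linked Gm29650 and Vamp7. Vamp7 was the 1 called gene without a match in the annotation used, so it was counted in no chromosome class. All 208 called genes had no overlap between the sexes, as did 9.35% of all genes, where chance gives 2.86%. The authors' deposited table lists 690 genes at an adjusted p under 0.05, of which 204 are among the 208, all in the same direction. The count rested on single hearts: it was 77 without female replicate 2, 110 without female replicate 3, 129 without female replicate 4, 137 without male replicate 1, 94 without male replicate 3, 84 without male replicate 4 and 516 without male replicate 5. DESeq2 on the recovered reads called 687 genes.

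Among the 10 named autosomal genes lower in females, C7 and Lvrn had the largest fold changes. C7, a component of the complement membrane attack complex, had 259 ± 41.2 in females and 1203 ± 169 in males (SD, n = 4 each), and fell by 2.21 on the log2 scale (limma adjusted p = 2.29e-05). Hsd11b1, which encodes the enzyme that regenerates active glucocorticoid, fell by 1.00, from 764 ± 52.6 in males to 383 ± 33.4 in females (limma adjusted p = 3.55e-05). The aminopeptidase gene Lvrn fell by 1.42, the chemokine gene Cxcl14 by 0.70 and Nkain1, whose product interacts with the sodium pump, by 0.67. Cib3, Hmmr, the calpain gene Capn3, Cpne7 and Mal fell by 0.96, 0.87, 0.78, 0.77 and 0.74. Capn3 shares its strand and position with Ganc, and Hsd11b1 lies opposite Lamb3, and the strand setting of the counting is not given, so the source of their reads is uncertain.

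Among the 10 named autosomal genes higher in females, Gal3st2 had the largest fold change, at a low level. It rose from 11.9 ± 0.836 in males to 28.3 ± 5.27 in females (SD, n = 4 each, log2 fold change 1.17, limma adjusted p = 0.0306). Kcne1, a subunit of the slow delayed rectifier potassium channel, rose from 561 ± 50.4 in males to 852 ± 128 in females (log2 fold change 0.59, limma adjusted p = 0.028). Htra4, Pdzrn4 and Dct rose by 0.66, 0.58 and 0.54. Smad9, a transducer of BMP signals, rose by 0.52, and Mamdc2, Prkcq, Pdzd2 and Adamtsl3 rose by 0.49, 0.48, 0.48 and 0.45. Of these 20 genes, 9 kept their call whichever heart was left out: Pdzrn4, Adamtsl3, C7, Lvrn, Hsd11b1, Capn3, Mal, Cxcl14 and Nkain1. The other 11 lost it in 3 to 7 of the 8 fits that left out 1 heart, and Cpne7 and Hmmr also with limma-voom. Among the 9, Pdzrn4, Adamtsl3, Capn3 and Mal lost it with blocks by library code number. Pdzrn4 and Adamtsl3 also lost it in the 5 hearts with the most reads. C7, Lvrn, Hsd11b1, Cxcl14 and Nkain1 kept it under all 21 alternatives.

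**Figure D2:**
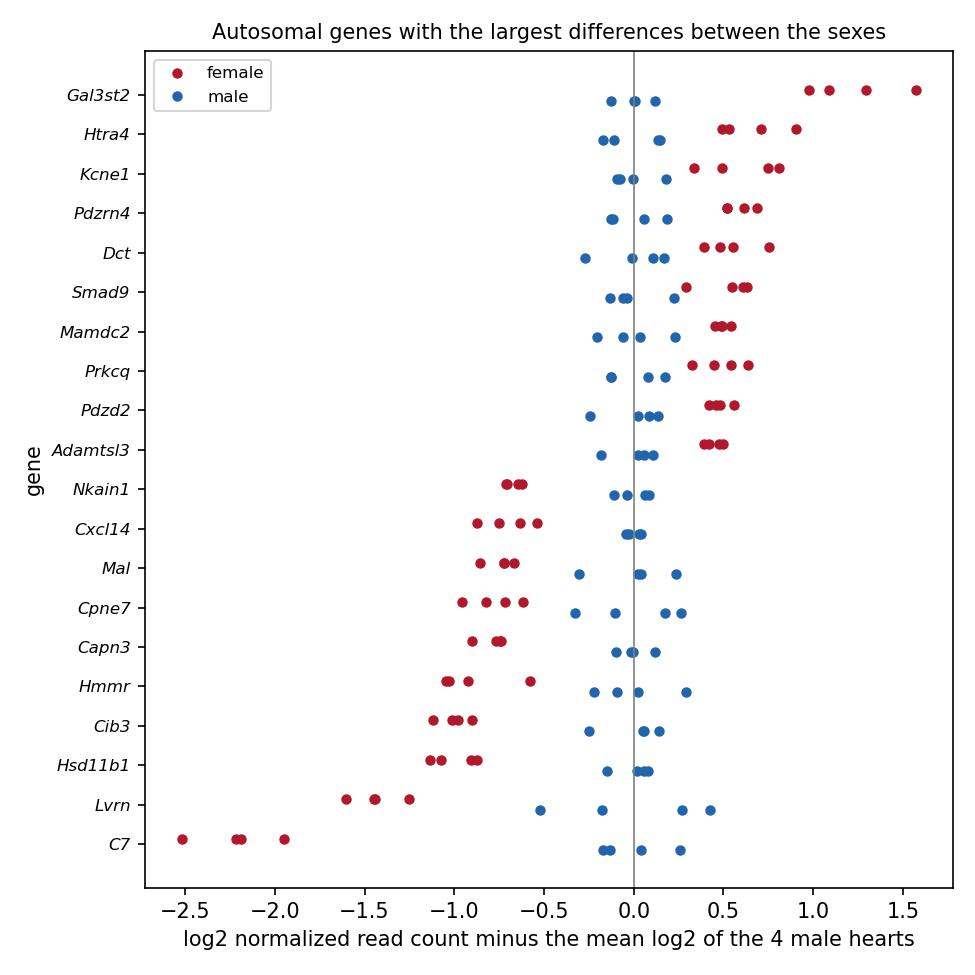
Log2 normalized read count of each heart minus the mean log2 of the 4 male hearts (horizontal axis) for the 10 autosomal genes with the largest rise and the 10 with the largest fall in females (vertical axis); each point is 1 heart. C7 lies furthest from the males, with a log2 fold change of -2.21.

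Among lists outside the sex chromosomes, calcium handling and ion channel genes and cardiac transcription factors pointed up in females in the list test, while most members did not pass. Of 34 calcium handling and ion channel genes, 4 rose (Slc8a1, Kcne1, Ryr2 and Atp2a2) and 30 did not pass; adjusted over the list alone, 13 rose and 1 fell. Slc8a1, the sodium-calcium exchanger, rose by 0.22, the calcium release channel gene Ryr2 by 0.20 and the calcium pump gene Atp2a2 by 0.17. The list median was 0.06 (camera adjusted p = 1.17e-04; adjusted p = 0.386 with an estimated correlation). Of 23 cardiac transcription factors, Myocd and Tbx20 rose by 0.27 and 0.21 and 21 did not pass; adjusted over the list alone, 5 rose. Their median was 0.11 (camera adjusted p = 1.16e-05; adjusted p = 0.0924 with an estimated correlation). With fry the adjusted p was 0.0248 for the cardiac transcription factors and 0.0806 for the calcium handling and ion channel genes. The score of the calcium list was 0.0748 to 0.118 in females and at most 0.0443 in males. The scores of the cardiac transcription factors overlapped between the sexes. Of the 8 fits without 1 heart, the calls ended in 3 for Kcne1, 5 for Slc8a1, 6 for Myocd and Tbx20, and 7 for Ryr2 and Atp2a2. That of Atp2a2 also ended with upper quartile factors in edgeR. With total reads as a covariate the calls of Kcne1, Ryr2, Atp2a2 and Myocd ended, and those of Slc8a1 and Tbx20 stayed. In the 5 hearts with the most reads only that of Slc8a1 stayed. Predicted genes overlap Atp2a2, so the source of its reads is uncertain.

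Macrophage, MHC class II and cell division lists pointed down in females in the list test, while their scores overlapped between the sexes. All 14 macrophage markers had negative fold changes, with a median of -0.30 (camera adjusted p = 7.40e-09; adjusted p = 0.386 with an estimated correlation). C1qa, Csf1r and C1qb fell by 0.41, 0.36 and 0.39 and 11 did not pass; adjusted over the list alone, 7 fell. Of the 8 fits without 1 heart, the calls ended in 6 for Csf1r and 7 for C1qa and C1qb. With total reads as a covariate the calls of Csf1r and C1qb ended and that of C1qa stayed. Csf1r also overlaps Hmgxb3, so the source of its reads is uncertain. Of 30 cell division genes, 28 had negative values (median -0.32, camera adjusted p = 1.64e-07; adjusted p = 0.699 with an estimated correlation). Hmmr fell and 29 did not pass; adjusted over the list alone, 2 fell, the other being Prc1 (-0.46). The call of Hmmr ended in 6 of the 8 fits without 1 heart, and also with a pseudocount of 0.1 and with limma-voom. All 9 MHC class II genes had negative values (median -0.50, camera adjusted p = 2.74e-04; adjusted p = 0.725 with an estimated correlation), and 0 passed in limma, over all genes or adjusted over the list alone. Cd74 had 5604 ± 1339 in females and 7948 ± 1538 in males (SD, n = 4 each). The exact permutation p of the score was 0.0857 for the macrophage list, 0.143 for the MHC class II list and 0.0857 for the cell division list (n = 4 each). With total reads as a covariate, chosen after seeing the data, the score difference went from -0.29 to -0.19 (SE 0.07), from -0.41 to -0.23 (SE 0.25) and from -0.32 to -0.22 (SE 0.11) in that order. The scores of these lists were lowest in female replicates 3 and 4, the macrophage scores being -0.45 and -0.36; those libraries and male replicate 5 (macrophage score -0.19) held the fewest reads.

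Heat shock, immediate early, fetal and mitochondrial genome lists pointed down in females in the list test, with 0 members passing in the main limma fit and scores that overlapped between the sexes. Of 16 heat shock genes 14 were negative (median -0.10, camera adjusted p = 7.53e-04; adjusted p = 0.409 with an estimated correlation); 0 passed, and adjusted over the list alone 2 fell, Hspb8 (log2 fold change -0.15) and Dnaja1 (-0.30). Of 22 immediate early genes 18 were negative (median -0.14, camera adjusted p = 0.0114; adjusted p = 0.726 with an estimated correlation); 0 passed, and adjusted over the list alone 2 fell, Jun (-0.46) and Nr4a3 (-0.84). Of 17 fetal and wall stress genes 11 were negative (median -0.05, camera adjusted p = 0.0456; adjusted p = 0.725 with an estimated correlation) and 0 passed, over all genes or adjusted over the list alone. Skeletal actin Acta1 had 10781 ± 2525 in females and 20949 ± 6653 in males, with a limma adjusted p = 0.193. All 13 mitochondrial genome genes were negative (median -0.12, camera adjusted p = 5.46e-04; adjusted p = 0.725 with an estimated correlation) and 0 passed, over all genes or adjusted over the list alone. Some mitochondrial protein genes, with mt-Atp8 of this list among them, had far lower counts than the others, as given below. The list was not tested without them. mt-Co1 had a log2 fold change of -0.13 and mt-Nd2 of -0.13. In the authors' deposited table Hspb8, Dnaja1, Jun, Nr4a3, Acta1 and mt-Co1 had an adjusted p under 0.05, and mt-Nd2 did not. Under the 21 alternatives each of those genes passed in 1 to 3, and mt-Nd2 in 0. In the 5 hearts with the most reads the mitochondrial median was -0.03 (camera adjusted p = 0.374). Without female replicate 3 or male replicate 4 the fetal list had camera adjusted p = 0.149 and 0.165, and without female replicate 1, male replicate 3 or male replicate 5 the immediate early list had 0.193, 0.0514 and 0.0891. Both calls also ended with the CPM filter (camera adjusted p = 0.082 and 0.0626), the fetal call with the library code block (0.104) and with total reads as a covariate (0.147), and the immediate early call in the 5 hearts with the most reads (0.0502).

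**Figure D3:**
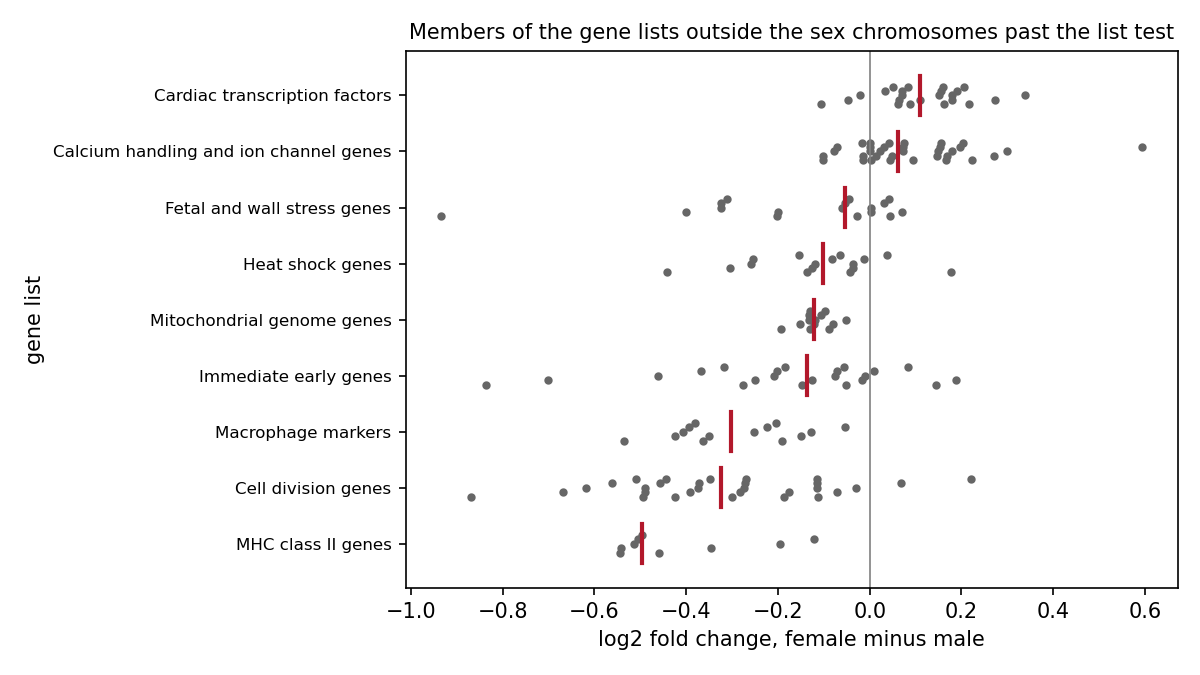
Log2 fold change, female minus male (horizontal axis), of the members of the 9 lists outside the sex chromosomes past the camera threshold (vertical axis); grey points are genes and red bars are list medians. The median lies at 0.11 for cardiac transcription factors and at -0.50 for MHC class II genes.

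Most metabolic genes did not pass and neither metabolic list passed the list test, while the called fatty acid use genes differed in direction. Of 37 fatty acid use genes 1 rose and 4 fell, and adjusted over the list alone 2 rose and 8 fell (camera adjusted p = 0.108). The mitochondrial carnitine carrier Slc25a20, Decr1 and Fabp3 fell by 0.22, 0.18 and 0.18, and the fatty acid transporter Slc27a1 rose by 0.28. The other gene that fell was Acads, an acyl-CoA dehydrogenase gene (log2 fold change -0.18), which was chosen after its values were seen and was not followed under the alternatives. Of 26 glucose use genes Pgam2 fell by 0.26, and adjusted over the list alone 2 fell (camera adjusted p = 0.179). Of 30 extracellular matrix genes Lum rose by 0.30 and Lox fell by 0.50, alike adjusted over the list alone (camera adjusted p = 0.0734). Of 11 sex hormone receptor and steroid enzyme genes Hsd11b1 fell, alike adjusted over the list alone (camera adjusted p = 0.906). Of the 8 fits without 1 heart, the calls ended in 5 for Decr1 and Fabp3 and 4 for Lox; Fabp3 also overlaps Zcchc17, so the source of its reads is uncertain.

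Lists of protein synthesis genes did not pass the list test. Of 35 DEAD-box helicase genes Ddx3x rose and Ddx3y fell, and adjusted over the list alone 2 rose and 3 fell (camera adjusted p = 0.398). Of 42 translation initiation factor genes Eif2s3x rose and Eif2s3y fell, and adjusted over the list alone 1 rose and 2 fell (camera adjusted p = 0.882). None of 40 cytosolic ribosomal protein genes passed, over all genes or adjusted over the list alone (camera adjusted p = 0.14). The DEAD-box list had a median of 0.006 and a mean of -0.22, with the camera test pointing up.

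Other heart muscle, clock and hormone response lists did not pass the list test. Among 12 cardiomyocyte markers Ryr2 rose, and adjusted over the list alone 2 rose and 2 fell (camera adjusted p = 0.906). None of 25 sarcomere genes passed, and adjusted over the list alone 1 fell (camera adjusted p = 0.906). None of 12 atrial markers passed (camera adjusted p = 0.882), nor any of 32 nuclear respiratory chain genes (0.14) or 18 glucocorticoid responsive genes (0.906), over all genes or adjusted over the list alone. The 18 circadian clock genes had a median of 0.12 (camera adjusted p = 0.473). The chemokine gene Cxcl9 fell by 0.53 among 27 interferon responsive genes, alike adjusted over the list alone (camera adjusted p = 0.539). Median and mean differed in sign for the sarcomere list (0.007 and -0.02) and the atrial list (-0.008 and 0.003); for the glucocorticoid list both were positive (0.02 and 0.0005) with the camera test pointing down.

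Markers of cell types other than macrophages, and of neighbouring tissues, did not pass the list test. Lum rose among 13 fibroblast markers, and adjusted over the list alone 2 rose (camera adjusted p = 0.169). The 7 thymocyte markers had a median of 0.18 and a mean of 0.22 while the camera test pointed down (camera adjusted p = 0.709). None of 16 fat markers (camera adjusted p = 0.593) or 12 skeletal muscle markers (0.14) passed, and adjusted over the list alone 1 fell in each. No gene passed, over all genes or adjusted over the list alone, among 15 endothelial markers (camera adjusted p = 0.539), 12 mural cell markers (0.14), 15 T and B cell markers (0.473) and 9 neutrophil and platelet markers (0.166). The same held for 8 red blood cell markers (camera adjusted p = 0.906), 14 epicardial and mesothelial markers (0.473), 13 neuron and Schwann cell markers (0.0929) and 6 lung and airway markers (0.615).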

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

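The tests in this part were chosen after the results were seen, and 2 of them, on total reads and on nuclear copies, were run in 2 versions, both given here. Splitting the 8 hearts into groups of 4 in every other way gave at most 3 called genes, and 1 of 35 splits, the real one, reached 208. For autosomal genes at most 2 were called in any other split, and 1 of 35 reached 185.

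Macrophage markers were lower in females as a list, but the score of the list overlapped between the sexes (exact permutation p = 0.0857, n = 4 each). A lower share of all cells other than muscle could lower them, but the score minus the mean of the fibroblast, endothelial and mural scores still differed by -0.31 (exact permutation p = 0.0286, n = 4 each), which argues against it. Fewer reads in the female libraries could also play a part. By the rule written first, that explanation failed: with total reads as a covariate the list median was -0.19 (camera adjusted p = 4.62e-07), beyond the bound of the rule, 0.5 of -0.30. A later version with the spread of the score left it open, at -0.19 (SE 0.07) with the covariate and -0.29 (SE 0.10) without; a difference between the sexes in macrophages themselves remains possible and was not tested.

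Of 13 mitochondrial protein genes, 6 had mean normalized read counts of 600 to 4136, against 407479 to 4986900 for the other 7. By the rule written first, reads shared with nuclear copies failed as the cause, since mt-Atp8 had 0% of its 50-base words in transcripts of nuclear genes. In a later version that set mt-Atp8 apart, mt-Nd3, mt-Atp6, mt-Co3, mt-Nd4l and mt-Co2 had at least 98.0% of their words there and the other 7 at most 62.2%, consistent with shared reads having been left out of the count. For mt-Atp8 the question stays open. It overlaps mt-Atp6, and the nuclear copies of its neighbours mt-Co2 and mt-Atp6 lie 233 bases apart, against 230 on the mitochondrial genome. No annotated transcript covers that nuclear stretch. Words were searched in annotated transcripts alone, so the 0% of mt-Atp8 cannot exclude a copy there. Loss of short transcripts is unlikely, since the longest low gene has 784 bases and the shortest other gene 519; no biological explanation was tested.

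In 10 of 238 groups of 4 hearts, 1 heart lay far from the other 3, where chance gives about 1 in 20. The normalized read count of Uty was 23.1 in female replicate 4 and at most 2.13 in the other females. Zfx was 1758 in male replicate 5, with the nearest male at 1631. Slc8a1 was 10760 in male replicate 5, with the nearest male at 9814. Capn3 was 94.1 in female replicate 2, with the nearest female at 104. mt-Atp8 was 512 in female replicate 4, with the nearest female at 571. Bub1b was 145 in female replicate 1, with the nearest female at 111. C1qb was 1870 in female replicate 3, with the nearest female at 2079. The score of fatty acid use genes was -0.0818 in female replicate 3, with the nearest female at 0.008. The score of endothelial markers was -0.0648 in male replicate 5, with the nearest male at 0.02. The score of thymocyte markers was 1.18 in male replicate 4, with the nearest male at -0.29.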

How the results depend on the processing

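All 208 called genes that a setting tested kept their direction in every setting. Since none of the 208 overlapped between the sexes, leaving out hearts, blocks, pseudocounts and filters could not have turned it. Only other scalings, count models and the covariate could have done so. Ddx3x kept its call in every setting (0.54 to 0.56 without 1 heart). Without 1 heart the calls ran from 77 to 516, higher from 30 to 239 and lower from 47 to 277; autosomal calls ran from 61 to 485, higher from 18 to 224 and lower from 41 to 261. The lowest counts came without female replicate 2 (autosomal higher: male replicate 4) and the highest without male replicate 5. DESeq2 on the recovered reads called 687 genes (304 higher, 383 lower), 646 of them autosomal (279 and 367). The thresholds stated in the labels were a log2 fold change over 0.6 in size and p under 0.05. Applied without adjustment for the number of genes, they gave 143 genes higher and 126 lower (autosomal: 126 and 115). The main test, with an adjusted p and no size limit, had 85 higher and 123 lower. In the authors' deposited values the unadjusted thresholds gave 132 higher and 110 lower. With an adjusted p under 0.05 and the same size limit, those values gave 16 higher and 41 lower. The other tests, scalings, pseudocounts and filters called 197 to 216 genes. Chosen after seeing the data, total reads as a covariate gave 156 calls (112 shared with the 208), 55 higher and 40 of those autosomal, and the 5 hearts with the most reads gave 155 (75 shared). Calls made up of higher genes were 40.9% of the total, and 30.9% without female replicate 3. The cause was not tested; fits without a heart also have fewer samples.

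Whether the numbers of the hearts pair them stays open, since each numbering gave few pairs and no test of pairing was run. Correlations of deviations were 0.22, -0.06 and -0.09 for hearts sharing a title number, and 0.22, -0.06 and 0.18 for a library code number. By library code number, female replicates 1 and 4 correlated best with the male of their number, and female replicate 3 did not. By title number only female replicate 1 did. Replicate blocks kept only hearts whose number occurs in both sexes, so these fits had fewer hearts than the main fit. The title number left out female replicate 2 and male replicate 5, and the library code number left out female replicate 2 and male replicate 4. A block by title number gave 145 calls (54 shared), 56 higher, 47 of those autosomal. By library code number it gave 28 calls (19 shared), 11 higher and 17 lower, and 19 of the 28 were autosomal (5 and 14). The effect of the block was not separated from that of the fewer hearts. Ddx3y had -8.06 (limma adjusted p = 0.214) and -8.10 (limma adjusted p = 0.366) under these blocks, and -9.07 to -7.79 without 1 heart. Of the 38 lists, 12 passed, and 12 to 17 without 1 heart, 20 with the title block, 0 with an estimated correlation and 4 with fry.

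The direction turned for Zfx with the covariate (-0.0108) and for Rbmx, which ran from -0.0233 to 0.0544 without 1 heart and had -0.0082 with the code block, -0.0368 with the covariate and -0.0224 in the 5 hearts with the most reads; neither was called, and the cause was not tested. Among other values of named genes 1340 were the same, 231 weaker and 32 stronger, and among lists 197 were the same and 31 weaker. The genes followed here were narrowed after a first run, in which uncalled members of lists without a call, such as Thy1 and Slc4a1, had changed sign. Genes with fewer than 81 reads over the 8 hearts were not in the table, under a filter that is not given in the sources used here, so what depth limits among low genes was not tested.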

Other observations

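The list of endothelial tip cell genes and its test were chosen after the calls were seen, and the test was run in 2 versions, both given here. Apln, Dll4 and Nid1, which mark endothelial tip cells of growing vessels, fell in females by 0.34, 0.29 and 0.29. Of 24 tip cell genes measured, 18 had negative log2 fold changes and 3 passed; adjusted over the list alone, 4 fell and 1 rose. The hypothesis that tip cell genes are lower in females as a set was tested on the 21 members that were not called, of which 15 were negative. The first version fitted it (camera p = 0.0409), while a later version with an estimated correlation left it open (p = 0.283), so the data suggest no more than a possible set change. Igfbp3 and Esm1 had the opposite sign (log2 fold changes of 0.46 and 0.33, neither called).

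Female replicate 4 held 68 reads of Ddx3y, 43 of Eif2s3y, 13 of Kdm5d and 19 of Uty, which is 1.40%, 1.28%, 1.14% and 1.60% of the mean normalized count of the male hearts. In the other females the share was 0.067% to 0.613%. Xist in the males was 1.43% to 1.75% of the female mean.

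In a principal component analysis the first component held 26.3% of the variance and the second 18.5%; the first separated the 4 females from the 4 males, as it did over autosomal genes alone (21.7%), and the second separated female replicates 3 and 4 and male replicate 5 from the other hearts.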
